A study of Homo sapiens with 12 samples.

How the data were processed

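Transcript levels were measured with 12 one-colour oligonucleotide arrays, 1 per culture of SW1463, a human colorectal adenocarcinoma cell line. The cultures formed 4 groups of 3: parental cells without irradiation, parental cells 6 h after a single dose of 4 Gy of X-rays, and radioresistant cells under the same 2 conditions. Per the labels, the radioresistant cells had received 34 cycles of 2 Gy, a cumulative dose of 68 Gy, and the 3 replicates of a group came from different passages. A single resistant line was made, so n counts cultures of that line and not independent selections.

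Per the file headers, the scanner files hold intensity values made by Agilent Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09 on array design 026652, whose annotation used human genome build hg19. The processed signal is the background-subtracted and detrended intensity, with no normalization between arrays. Other columns per the file headers hold the raw median spot and local background intensity and flags of 0 or 1 for spots that are outliers or well above background. The deposited value table is on a log2 scale and lists 24350 of the 34127 probes. On each array it was a nearly linear function of the log2 processed signal, with a correlation of at least 0.997. The normalization behind that table was not stated, and it served as an alternative only.

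Control spots and spots marked as outliers were left out, signals under 1 were set to 1, and replicate spots of a probe were averaged. Values were log2 transformed and the 75th percentile of each array was subtracted. A probe was tested if it was well above background on all 3 arrays of at least 1 group, and each gene was represented by its brightest probe. Of the 34127 probes, 26449 carried a RefSeq accession matched to 1 gene symbol, 0 matched several and 7678 matched none. The symbols came from the RefSeq annotation of GRCh38.p14. Because the array design used another build, that annotation supplied names only and no coordinates. The filter left 17976 genes or unnamed probes, of which 38 lacked a value on some array and were left out of the list tests.

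The groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group fitted to all 12 arrays, moderated two-sided tests and Benjamini-Hochberg adjustment over all genes tested. Adjusted p under 0.05 was the threshold. There were 6 comparisons: resistant against parental cells without irradiation, the same 6 h after 4 Gy, 4 Gy against none in each line, the difference of both 4 Gy responses, and their mean. The fit had 8 residual degrees of freedom, a prior of 2.98 and a median residual SD of 0.476 on the log2 scale. The array's signal over background, given per array with the data, and the number of arrays limit the precision.

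A total of 29 gene lists were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. The lists covered Wnt/beta-catenin targets and Wnt pathway components, G2/M, DNA replication, double-strand break repair, apoptosis, histones, interferon-stimulated genes, HLA, NF-kappaB, immediate early genes, NRF2, unfolded protein response, hypoxia, cholesterol synthesis, drug transport, stem cell markers, enterocyte, goblet and enteroendocrine genes, Notch, BMP and TGF-beta, receptor tyrosine kinases, epithelial and mesenchymal genes, and markers of blood, stromal, endothelial and neural cells. Adjustment was over the 29 lists of a comparison. Each list was also tested with an estimated correlation and with fry, a rotation test of whether its genes moved, on balance, one way. A list median is the median over its tested genes, and 13 list genes had no probe. Genes were named by a rule: up to 12 called genes in each direction for the unirradiated lines and up to 8 for the other comparisons, up to 4 members with the smallest p of each list described, and always CTNNB1, AXIN2, LGR5, TCF7L2, CDKN1A, MDM2, MYC, CCND1 and APC. The text names a part of the genes so chosen, and 1 list and some of the genes are not reported here. A gene not well above background in a group was to be given as a lower bound. The groups, tests, lists, naming rule and the alternatives listed next were chosen before the data were examined.

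The alternatives were quantile and median scaling, normexp background correction with an offset of 50 followed by quantile scaling, no filter and a stricter filter on all 12 arrays, the mean of a gene's probes, each probe by itself, outlier spots kept, the deposited value table, slide as a random or fixed block, slide run as a covariate, the replicate number as a block, array weights, a trended robust prior, only the 6 arrays compared, thresholds of adjusted p under 0.01 or an added log2 change of 1, and each array left out in turn. The normexp setting used the median spot intensity because the deposited columns hold no mean spot intensity. After the data were seen, scan day as a fixed or random block was added, and fits without parental 0 Gy array 2 and resistant 4 Gy array 1, and without parental 4 Gy arrays 2 and 3. The headers gave 7 slides and 5 scan days. The 2 runs of slides were inferred from the first part of the slide barcodes. Run 2 held only parental arrays, 0 Gy array 1 and 4 Gy arrays 2 and 3, so run and line are partly confounded. For list tests under random blocks or a trended prior, the moderated statistics were turned into z-scores and tested at the same preset correlation.

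The procedure was tested on simulated arrays of 17938 genes, with noise drawn independently for each gene at its fitted spread. Changes were added to the simulated arrays of unirradiated resistant cells, and no slide effects were simulated. Of 50 genes changed by 1 log2 unit 2 were recovered, of 50 changed by 2 units 27, of 50 changed by 3 units 42 and of 50 changed by 4 units 48, with 5 false calls. A shift of 0.5 in the 26 tested Wnt target genes was called, with 0 calls among the other lists. Since the simulated noise was independent between genes, this cannot show how the list test behaves with correlated genes. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.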

Results

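Transcript levels were measured on 12 arrays of SW1463 cells, 3 each of parental cells without irradiation (parental 0 Gy), parental cells 6 h after 4 Gy (parental 4 Gy), radioresistant cells without irradiation (resistant 0 Gy) and radioresistant cells 6 h after 4 Gy (resistant 4 Gy). Of the probes besides controls, 62.4% to 83.9% were well above background on each array. The median processed signal was 53.3 to 92.1 intensity units on 9 arrays, 196 on parental 0 Gy array 3, and 212 and 257 on parental 4 Gy arrays 2 and 3, which shared a slide. Net signal of the negative controls was 152 and 137 intensity units on the latter pair, 96.6 on parental 0 Gy array 3, and lower, down to 18.6, on the others. The number of arrays limits the precision of every value given here. Differences are on the log2 scale and carry the standard error of the fit with n = 3 arrays per group. Levels are log2 signals relative to the 75th percentile of the array, given as mean ± SD (n = 3). List levels per array are relative to the mean of the 12 arrays.

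The comparison of both lines without an acute dose asked which genes separated the radioresistant cells from their parents. Genes of DNA replication and S phase were higher in the resistant cells, 35 of 36 of them, with a median difference of 0.43 (adjusted p = 1.35e-06, adjusted p = 0.698 with an estimated correlation). CCNE1, encoding the cyclin that drives entry into S phase, differed by 0.88 ± 0.48. CDC6, which loads the replicative helicase onto origins, differed by 0.76 ± 0.44 and POLA1, the catalytic subunit of DNA polymerase alpha, by 0.61 ± 0.38. Genes of G2/M and mitosis were higher in 33 of 36 cases with a median of 0.38 (adjusted p = 0.00346, adjusted p = 0.698 with an estimated correlation). Among them CDC20, an activator of the anaphase-promoting complex, differed by 0.63 ± 0.51. Genes of double-strand break repair and checkpoint were higher in 26 of 37 cases with a median of 0.22 (adjusted p = 0.00346, adjusted p = 0.698 with an estimated correlation). In that list H2AX, the histone variant phosphorylated at breaks, differed by 0.50 ± 0.32, whereas NHEJ1, a factor of end joining, differed by -0.55 ± 0.34. CDC6 was at 0.37, POLA1 at 0.34 and H2AX at 0.25 without parental 0 Gy array 1, and CDC20 at 0.34 without resistant 0 Gy array 1.

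Drug transport and fluoropyrimidine genes were higher in resistant cells in 14 of 20 cases, with a median of 0.27 (adjusted p = 0.0154, adjusted p = 0.193 with an estimated correlation). The efflux pump gene ABCG2 differed by 0.95 ± 0.39 and UMPS, which makes uridine monophosphate and activates fluorouracil, by 0.68 ± 0.30. CDA, the cytidine deaminase, differed by -0.90 ± 0.32. NRF2 and antioxidant genes were higher in 21 of 27 cases with a median of 0.13 (adjusted p = 0.0154, adjusted p = 0.193 with an estimated correlation). MGST1, a microsomal glutathione transferase, differed by 0.54 ± 0.33 and GPX1, a glutathione peroxidase, by 0.44 ± 0.34. Stem cell and tumour-initiating cell markers were higher in 12 of 20 cases with a median of 0.14 (adjusted p = 0.0479, adjusted p = 0.280 with an estimated correlation). ALDH1A1, an aldehyde dehydrogenase used as such a marker, differed by 0.71 ± 0.39, and TERT, the telomerase reverse transcriptase, by 0.44 ± 0.29. ABCG2 was at 0.56, UMPS at 0.43 and MGST1 at 0.25 without parental 0 Gy array 1, GPX1 at 0.22 without array 3 and ALDH1A1 at 1.08 without array 2 of that group.

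Enterocyte differentiation genes were lower in the resistant cells in 18 of 26 cases, with a median of -0.49 (adjusted p = 0.0270, adjusted p = 0.698 with an estimated correlation). CDHR5, a protocadherin of the brush border, differed by -1.28 ± 0.51. SLC26A3, the chloride and bicarbonate exchanger of the colonic surface, differed by -1.34 ± 0.59 and PLAC8 by -1.31 ± 0.44. HLA and antigen presentation genes were lower in 16 of 18 cases with a median of -0.37 (adjusted p = 0.0152, adjusted p = 0.698 with an estimated correlation). CD74, the invariant chain of class II molecules, differed by -1.53 ± 0.97 and HLA-B by -1.28 ± 0.78. Single arrays carried much of both, since CD74 was at -0.89 without parental 0 Gy array 3 and HLA-B at -0.46 without array 1 and -2.02 without array 2 of that group. CDHR5 was at -0.81 without parental 0 Gy array 1. Binding of the HLA-B probe to other class I genes was not tested. With median scaling, which moved the median of all genes from -0.07 to 0.43, the enterocyte median became 0.00 and the HLA median 0.12.

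By limma, 0 of 17976 genes passed the threshold without irradiation, and the smallest adjusted p was 0.993. At an unadjusted p under 0.05 lay 308 genes, 73 higher and 235 lower, where 899 would be expected with no difference, in this as in each comparison. All 9 list calls were lost with an estimated correlation and with fry, 6 were lost with quantile scaling, and 5 each with normexp, with slide as a fixed block and without parental 0 Gy array 3. Leaving out parental 0 Gy array 1 alone also lost 5 calls, with G2/M at 0.05 (adjusted p = 0.256), break repair at 0.01 (adjusted p = 0.351), HLA genes at -0.09 (adjusted p = 0.548) and enterocyte genes at -0.40 (adjusted p = 0.0705). That array was low in G2/M, at -0.15 against 0.88 and 0.86 on the other parental 0 Gy arrays, and in replication, at -0.35 against 0.56 and 0.29. Replication genes were at 0.20 within slide run 1, 3 resistant against 2 parental arrays. With slide run as a covariate 5 calls were lost and G2/M turned to -0.27. Within scan day 2, the medians of 1 resistant against 2 parental arrays were 0.02 for replication, -0.08 for G2/M, -0.35 for enterocyte genes and -0.24 for HLA genes. Within slide 4, 1 array against 1, they were 0.20, -0.07, -0.77 and -0.40. The 2 parental arrays of slide run 1 and of scan day 2 were arrays 2 and 3. Array 2 had the levels of resistant cells in many genes, as described below, which limits what these values show. Some markers of other cells were lower without a call, blood cell markers at -0.40 (adjusted p = 0.208) and endothelial and neural markers at -0.42 (adjusted p = 0.518). Within slide 4 these were at -1.36 and -1.13. Stromal markers hardly moved, with mean array medians of -0.22 in resistant and -0.25 in parental 0 Gy cells and -0.03 within slide 4. The parental array of slide 4, array 3, had a negative control signal of 96.6, and an effect of background on dim probes was not tested.

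Wnt/beta-catenin target genes, the list set for the pathway in the title of the series, were higher in unirradiated resistant cells in 17 of 26 cases. Their median difference was 0.15 and their mean 0.27 (adjusted p = 0.0154, adjusted p = 0.698 with an estimated correlation). Of the 26 genes, 0 passed when adjusted over the list alone. LEF1, a transcription factor that binds beta-catenin, stood at 1.24 ± 0.10 in resistant 0 Gy and -0.32 ± 1.16 in parental 0 Gy cells, a difference of 1.56 ± 0.60. SP5, a transcription factor induced by Wnt signals, differed by 0.69 ± 0.39. NKD1, a feedback inhibitor, differed by 0.53 ± 0.28, MYC by 0.49 ± 0.28, and ETS2 by -0.68 ± 0.36. AXIN2, another feedback inhibitor, differed by 0.14 ± 0.42, with overlapping levels of 1.722 to 2.575 on the resistant and 1.892 to 2.199 on the parental 0 Gy arrays. LGR5, a receptor for R-spondins on intestinal stem cells, differed by 0.50 ± 0.84, and CCND1, encoding cyclin D1, by -0.06 ± 0.26. MYC was at 0.26 and LGR5 at 0.10 without parental 0 Gy array 1, and LGR5 at 0.83 without array 2 of that group. The level of LEF1 was 1.01 on parental 0 Gy array 2, against -1.07 and -0.91 on arrays 1 and 3. Array 2 thus lowered the difference of LEF1 and did not carry it.

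The 43 tested Wnt pathway components had a median of 0.03 and a mean of -0.03 in the same comparison, of opposite sign, and were not called (adjusted p = 0.303). Among them CTNNB1, encoding beta-catenin, differed by 0.31 ± 0.31 with its probes of opposite sign, TCF7L2 by -0.14 ± 0.30, and APC, the scaffold of the destruction complex, by -1.13 ± 0.93, well above background on 2 of 3 resistant arrays. Single arrays moved APC to -2.18 (without parental 0 Gy array 2), -0.31 (without parental 0 Gy array 3) and -0.63 (without resistant 0 Gy array 1), and CTNNB1 to 0.50 and 0.20 (without resistant 0 Gy arrays 1 and 3). The call for the target genes was lost without parental 0 Gy array 3, at 0.16 (adjusted p = 0.239), without resistant 0 Gy array 2, at 0.09 (adjusted p = 0.121), and with quantile scaling, at 0.17 (adjusted p = 0.367). Slide run as a covariate gave -0.05 (adjusted p = 0.402). Without parental 0 Gy array 2 and resistant 4 Gy array 1 together, a choice made after the data were seen, the median was 0.24 (adjusted p = 0.00332). Within slide 4 the median was 0.24. Within scan day 2 it was 0.16, with parental 0 Gy array 2, which had resistant levels in many genes, on the parental side.

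A set of genes, chosen after its values were seen, had levels in 2 separate ranges that did not follow the labels. PRAC1, a gene expressed in the prostate, rectum and distal colon, lay between 2.32 and 5.24 on parental 0 Gy arrays 1 and 3, the 3 parental 4 Gy arrays and resistant 4 Gy array 1. On parental 0 Gy array 2 and the other 5 resistant arrays PRAC1 lay between -2.52 and -1.41. H19, an imprinted noncoding RNA, was at 4.52 on parental 0 Gy array 2 and at 0.42 on resistant 4 Gy array 1. It was at 3.87 to 5.08 on the other resistant and -4.03 to 0.92 on the other parental arrays. CEACAM6, an adhesion molecule of colorectal tumours, was at -0.49 on parental 0 Gy array 2 and at -6.11 on resistant 4 Gy array 1. The range was -1.68 to -0.17 on the other resistant and -5.62 to -3.85 on the other parental arrays. In all, 16 genes had a gap of over 2 log2 units between the 6th and the 7th array. All 16 parted the arrays in this way, and 0 parted the line labels. Across genes, which are not independent replicates, parental 0 Gy array 2 correlated most with resistant 4 Gy array 2 (Pearson r = 0.992). Its correlation with parental 0 Gy arrays 1 and 3 was 0.955 and 0.951, and with parental 4 Gy array 1 it was 0.973. Parental 0 Gy arrays 1 and 3 correlated with each other at only 0.956, so the lower values do not set array 2 apart from its group.

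**Figure D1:**
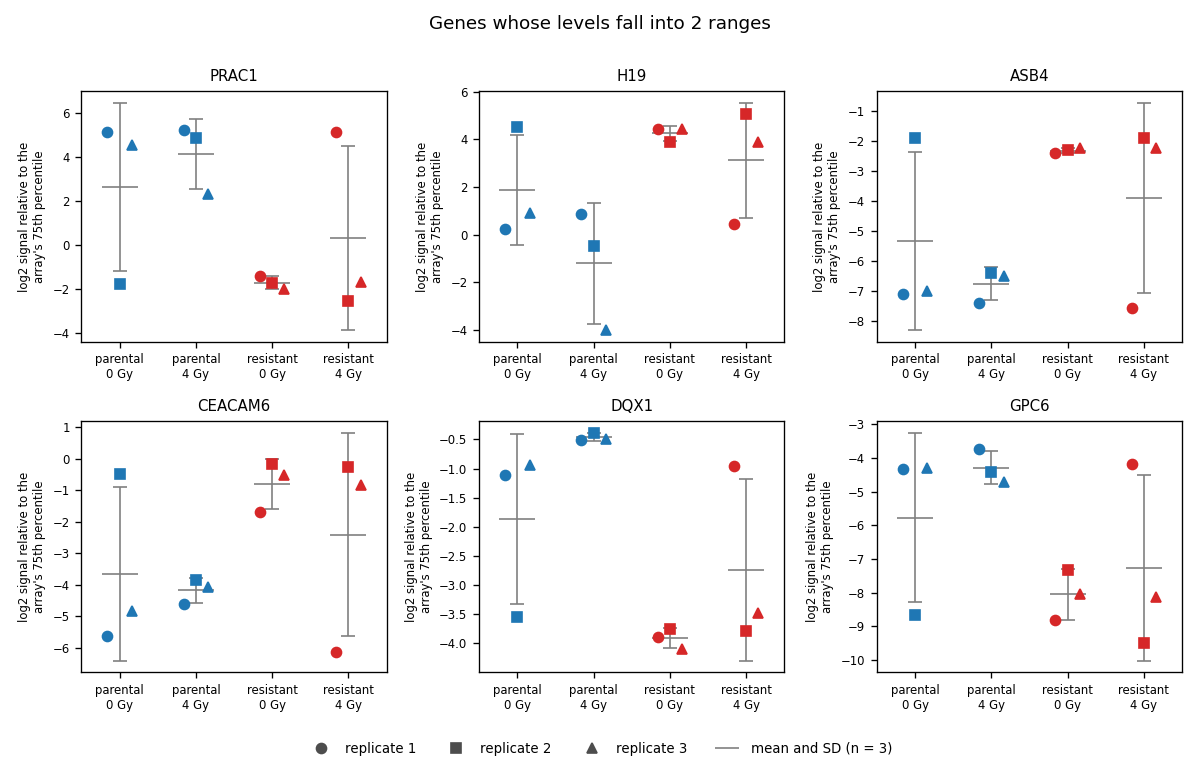
Levels of 6 genes on each of the 12 arrays by group, as log2 signal relative to the 75th percentile of the array, with points for replicates and bars for mean and SD (n = 3). PRAC1, DQX1 and GPC6 were low and H19, ASB4 and CEACAM6 high on parental 0 Gy array 2 and on 5 of the 6 resistant arrays, and resistant 4 Gy array 1 lay with the other parental arrays.

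In fits without these 2 arrays, chosen after the data were seen, 11 genes passed the threshold without irradiation, 5 higher and 6 lower in resistant cells. The p-values are too small for the genes that led to the choice. The 5 higher genes were ASB4, at least 8.88-fold higher, CEACAM6 at 4.43 ± 0.50, well above background on 1 of 2 parental arrays, KLK7, a secreted serine protease, at 3.43 ± 0.39, LOC646903, at least 2.95-fold higher, and TTC39C at 2.06 ± 0.26. The 6 lower were PRAC1 at -6.56 ± 0.76, GBA3, a cytosolic beta-glucosidase, at -3.04 ± 0.39, DQX1 at -2.89 ± 0.27, EGFL6 at -2.48 ± 0.32, HSD52, at least 5.42-fold lower, and an unnamed probe at -3.13 ± 0.30. Of the 3 resistant arrays, GBA3 and the unnamed probe were well above background on 1 and EGFL6 on 2, so these differences are uncertain in size. Of these, 9 were also among the 70 genes called 6 h after 4 Gy on the other arrays, in the same direction. These include genes that led to the choice, so the overlap is no independent test.

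After 4 Gy, the comparison of the lines asked what separated them 6 h into the response. All 36 G2/M and mitosis genes were higher in resistant cells, with a median of 2.66 (adjusted p = 3.59e-21, adjusted p = 0.380 with an estimated correlation). Adjusted over the list alone 36 of 36 passed, against 0 over all genes. The SD of the list's array medians was 2.07 in parental 4 Gy, against 0.24 to 0.59 in the other groups. Since the fit pools the spread, these passes overstate the certainty. CENPE, a motor of the kinetochore, stood at -0.03 ± 0.46 in resistant and -2.68 ± 1.52 in parental cells, a difference of 2.65 ± 0.64. KIF23, a kinesin of cytokinesis, differed by 2.12 ± 0.54. All 36 replication genes were higher with a median of 1.79 (adjusted p = 3.61e-17, adjusted p = 0.380 with an estimated correlation). Of these, 28 passed when adjusted over the list alone. CCNE1 differed by 2.10 ± 0.48 and MCM4, a subunit of the replicative helicase, by 1.89 ± 0.53. Double-strand break repair genes were higher in 32 of 37 cases with a median of 0.78 (adjusted p = 1.69e-06, adjusted p = 0.380 with an estimated correlation). FANCD2 of the Fanconi pathway differed by 1.52 ± 0.46 and MDC1, a checkpoint mediator, by 0.93 ± 0.28.

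Wnt target genes were higher in irradiated resistant cells in 23 of 26 cases with a median of 0.73 (adjusted p = 1.69e-05, adjusted p = 0.380 with an estimated correlation). LGR5 stood at -2.46 ± 0.84 in resistant and -5.10 ± 2.03 in parental cells, a difference of 2.64 ± 0.84 of uncertain size, since only 2 of 3 parental 4 Gy arrays were well above background. LEF1 differed by 2.05 ± 0.60, CEMIP, a hyaluronan-degrading protein, by 2.46 ± 0.86 and MYC by 0.77 ± 0.28. On resistant 4 Gy array 1 LEF1 was at -0.64, against 0.86 and 1.43 on arrays 2 and 3. Without that array and parental 0 Gy array 2, a choice made after the data were seen, LEF1 differed by 2.64 ± 0.33. Interferon-stimulated genes were higher in 27 of 34 cases with a median of 0.46 (adjusted p = 0.00485, adjusted p = 0.648 with an estimated correlation). This rested on resistant 4 Gy array 3, without which the median was -0.02 (adjusted p = 0.631). Drug transport genes were higher in 13 of 20 cases with a median of 0.43 (adjusted p = 0.0342, adjusted p = 0.380 with an estimated correlation). It was the 1 list also called by fry (adjusted p = 0.0363). UMPS differed by 1.09 ± 0.30 and SLC29A1, a nucleoside transporter, by 1.81 ± 0.57. LGR5 was at 1.52, CEMIP at 1.41 and SLC29A1 at 1.13 without parental 4 Gy array 3.

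On parental 4 Gy arrays 2 and 3, which carried the low G2/M levels of -1.55 and -4.24, the markers of other cell types were high. Blood cell markers were at 1.08 and 0.94, endothelial and neural markers at 1.22 and 1.51, and stromal markers at 0.50 and 0.91. Both arrays had the highest net signals of negative controls, 152 and 137, and an effect of background on dim probes was not tested. Without these 2 arrays the parental 4 Gy group was 1 array, assumed to vary like the others. The medians were then 0.79 for G2/M, 0.68 for replication and 0.14 for Wnt targets, whose call was lost. By limma, 0 of 17976 genes passed after 4 Gy, and the smallest adjusted p was 0.130. At an unadjusted p under 0.05 lay 4627 genes, 1598 higher and 3029 lower. Once parental 4 Gy array 1 was left out, 4679 genes passed. That left only arrays 2 and 3 of the group, which shared a slide, so line and slide could not be told apart. With slide as a fixed block 0 of the 6 list calls were kept and G2/M was at 0.28. The slide of parental 4 Gy arrays 2 and 3 held no other array, so that fit takes both up in the slide term. Only array 1 then stands for irradiated parental cells, so the lost calls do not part slide from line. Within scan day 1, 1 array against 1, the medians were 0.62 for G2/M, 1.08 for replication, 0.53 for break repair, 0.38 for Wnt targets, 0.96 for interferon-stimulated genes and 0.44 for drug transport. The resistant array of that pair is array 3, the one that carries the interferon difference.

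**Figure D2:**
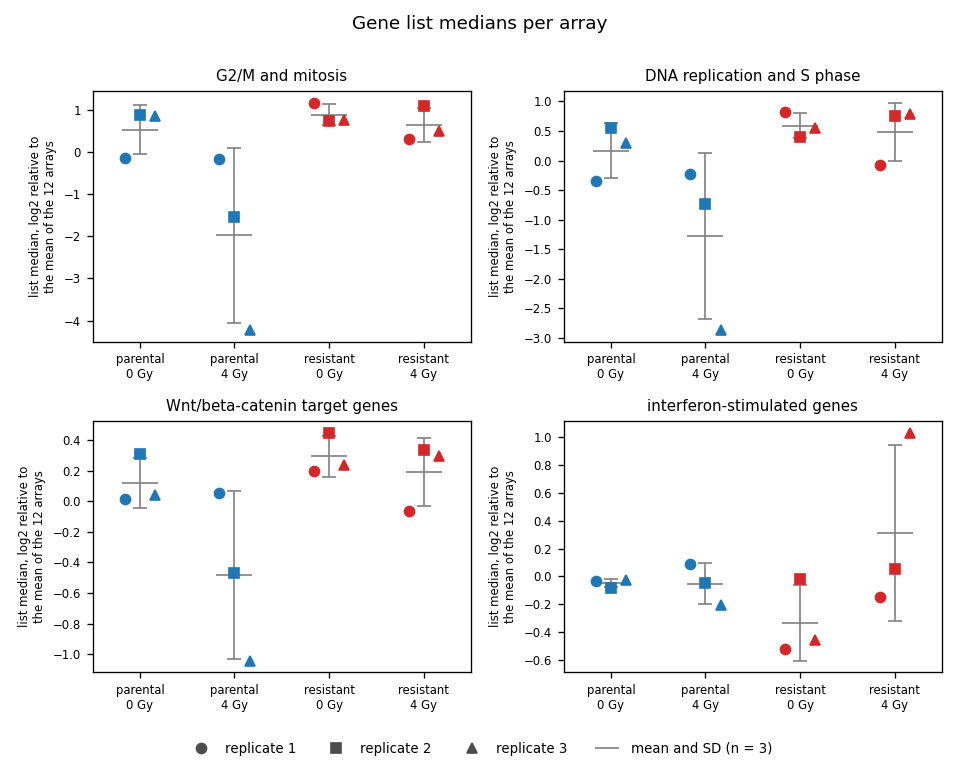
Medians of 4 gene lists on each of the 12 arrays by group, as log2 relative to the mean of the 12 arrays, with points for replicates and bars for mean and SD (n = 3). The G2/M median of the parental 4 Gy arrays was -0.16, -1.55 and -4.24, and that of the other 9 arrays lay between -0.15 and 1.17.

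The response of parental cells to 4 Gy asked which genes changed within 6 h of a single dose. All 36 G2/M and mitosis genes were lower after 4 Gy, with a median of -2.64 (adjusted p = 3.56e-26, adjusted p = 0.396 with an estimated correlation). When adjusted over the list alone, 36 of 36 passed, which overstates the certainty because the pooled spread is below that of the parental 4 Gy arrays. CCNB1, encoding cyclin B1 that drives entry into mitosis, stood at 0.85 ± 1.87 after 4 Gy and 3.71 ± 0.66 without, a difference of -2.86 ± 0.74. CENPE differed by -2.67 ± 0.64 and CDC20 by -1.86 ± 0.51. Replication genes were lower in 35 of 36 cases with a median of -1.49 (adjusted p = 1.26e-16, adjusted p = 0.399 with an estimated correlation). CCNE1 differed by -1.51 ± 0.48 and RRM2, a subunit of ribonucleotide reductase, by -2.40 ± 0.84. Double-strand break repair genes were lower in 32 of 37 cases with a median of -0.68 (adjusted p = 9.02e-08, adjusted p = 0.396 with an estimated correlation). BARD1, the partner of BRCA1, differed by -1.73 ± 0.65. Wnt target genes were lower in 24 of 26 cases with a median of -0.66 (adjusted p = 2.21e-06, adjusted p = 0.396 with an estimated correlation). MYC differed by -0.71 ± 0.28, EPHB3, an ephrin receptor of the crypt, by -1.38 ± 0.55 and LGR5, well above background on 2 of 3 irradiated arrays, by -2.26 ± 0.84. Parental 4 Gy array 3 carried much of these values, and without it RRM2 was at -1.38, BARD1 at -0.90, EPHB3 at -0.64 and LGR5 at -1.14.

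In parental cells CDKN1A, an inhibitor of cyclin-dependent kinases, differed by 0.30 ± 0.57 and MDM2, a ubiquitin ligase, by -0.00 ± 0.28 with its probes of opposite sign. CDKN1A lay at -3.18, -3.06 and -1.73 on the 4 Gy arrays and at -3.14, -3.74 and -1.97 on the 0 Gy arrays, so array 3 of each group moved its difference. Without parental 4 Gy arrays 2 and 3 only array 1 of that group was left. The medians were then -0.67 for G2/M, -0.38 for replication, -0.28 for break repair and -0.02 for Wnt targets, whose call was lost. Array 1 had a G2/M median of -0.16, next to -0.15 on parental 0 Gy array 1. By limma, 0 of 17976 genes passed, and the smallest adjusted p was 0.237. At an unadjusted p under 0.05 lay 2522 genes, 1715 higher and 807 lower. Once parental 4 Gy array 1 was left out, 2465 genes passed. Only arrays 2 and 3, which shared a slide, then stood for 4 Gy, so dose and slide could not be told apart. With slide as a fixed block the break repair and Wnt calls were lost. That block takes up arrays 2 and 3, alone on their slide, and leaves array 1 to stand for 4 Gy. Slide runs 1 and 2, each with at most 2 arrays of a group, gave -0.98 and -2.83 for G2/M, -0.62 and -1.38 for replication, -0.46 and -0.45 for break repair and -0.06 and -0.73 for Wnt targets.

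In resistant cells the same dose asked what the selected line changed within 6 h. All 34 interferon-stimulated genes were higher after 4 Gy with a median of 0.64 (adjusted p = 8.45e-15, adjusted p = 0.352 with an estimated correlation). MX1, an antiviral GTPase, stood at 1.68 ± 1.64 after 4 Gy and 0.15 ± 0.71 without, a difference of 1.53 ± 0.70. IRF9, a transcription factor of interferon signalling, differed by 1.34 ± 0.57 and RIGI, a sensor of viral RNA, by 0.81 ± 0.36. MX1 was at 0.60, IRF9 at 0.66 and RIGI at 0.39 without resistant 4 Gy array 3. HLA and antigen presentation genes were higher in 16 of 18 cases with a median of 0.24 (adjusted p = 0.00764, adjusted p = 0.686 with an estimated correlation). Cholesterol synthesis genes were higher in 22 of 25 cases with a median of 0.17 (adjusted p = 0.00764, adjusted p = 0.699 with an estimated correlation). TAP1, a peptide transporter, differed by 0.41 ± 0.30, and LSS, the lanosterol synthase, by 0.63 ± 0.33.

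Immediate early genes were lower in irradiated resistant cells in 20 of 24 cases with a median of -0.25 (adjusted p = 0.00187, adjusted p = 0.686 with an estimated correlation). FOS differed by -1.25 ± 0.66, EGR1 by -0.91 ± 0.61 and DUSP6, a phosphatase of ERK, by -0.60 ± 0.35. Stem cell markers were lower in 15 of 20 cases with a median of -0.37 (adjusted p = 0.00247, adjusted p = 0.116 with an estimated correlation), TERT among them at -0.52 ± 0.29. BMP and TGF-beta genes were lower in 16 of 23 cases with a median of -0.18 (adjusted p = 0.0161, adjusted p = 0.686 with an estimated correlation). ID2, a target of BMP signals, differed by -0.98 ± 0.57. G2/M genes were lower in 31 of 36 cases with a median of -0.30 (adjusted p = 0.0161, adjusted p = 0.951 with an estimated correlation). Replication genes were lower in 26 of 36 with a median of -0.18 (adjusted p = 0.0256, adjusted p = 0.951 with an estimated correlation). Break repair genes were lower in 28 of 37 cases with a median of -0.13 (adjusted p = 0.00764, adjusted p = 0.764 with an estimated correlation). Wnt targets were lower in 17 of 26 with a median of -0.14 (adjusted p = 0.0383, adjusted p = 0.847 with an estimated correlation). FOS was at -0.66 without resistant 0 Gy array 1, EGR1 at -0.59 without resistant 4 Gy array 2, and DUSP6 at -0.34 and ID2 at -0.36 without resistant 4 Gy array 1.

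The interferon median of resistant 4 Gy array 3 was 1.03, against -0.15 and 0.05 on the other irradiated and -0.52 to -0.02 on the unirradiated resistant arrays. Without that array the difference was 0.25 (adjusted p = 0.00581). By limma, 0 of 17976 genes passed in resistant cells, and the smallest adjusted p was 1. At an unadjusted p under 0.05 lay 171 genes, 143 higher and 28 lower, fewer than the 899 expected with no difference. Without parental 0 Gy array 2 and resistant 4 Gy array 1 the interferon and immediate early calls were kept. Of the 10 calls 7 were lost, as they were without resistant 4 Gy array 1 alone, and replication turned to 0.10 (adjusted p = 0.591). Median scaling lost 4 of the 10 calls, quantile scaling 3, normexp 3 and leaving out resistant 0 Gy array 2 lost 4. Within scan day 1, 1 irradiated against 2 unirradiated arrays, and within scan day 2, 1 against 1, the interferon medians were 1.62 and -0.18. There the stem cell medians were -0.39 and -0.35, the immediate early medians -0.23 and -0.66 and the G2/M medians -0.50 and -0.52. The irradiated array was array 3 on day 1 and array 1, which carries parental levels, on day 2.

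The difference of the 4 Gy responses, resistant minus parental, asked whether the lines responded alike. It was positive for all 36 G2/M genes with a median of 2.37 (adjusted p = 8.55e-21, adjusted p = 0.720 with an estimated correlation). It was positive for 35 of 36 replication genes with a median of 1.31 (adjusted p = 8.35e-12, adjusted p = 0.720 with an estimated correlation) and for 32 of 37 break repair genes with a median of 0.39 (adjusted p = 0.000473, adjusted p = 0.720 with an estimated correlation). PLK1, a kinase of mitosis, stood at 1.11 ± 1.04 in resistant 4 Gy, 0.81 ± 0.61 in resistant 0 Gy, -1.80 ± 1.89 in parental 4 Gy and 0.91 ± 0.26 in parental 0 Gy cells. Its difference of responses was 3.00 ± 1.14. It was also positive for 32 of 34 interferon-stimulated genes with a median of 0.64 (adjusted p = 2.35e-06, adjusted p = 0.720 with an estimated correlation), with IFIT3 at 1.38 ± 0.68. Of the Wnt targets 24 of 26 were positive with a median of 0.45 (adjusted p = 0.00124, adjusted p = 0.720 with an estimated correlation), with EPHB3 at 1.52 ± 0.77. The difference was negative for 23 of 24 genes of the unfolded protein response with a median of -0.57 (adjusted p = 0.00274, adjusted p = 0.736 with an estimated correlation), with ATF4, a stress transcription factor, at -0.71 ± 0.43. Immediate early genes were negative in 18 of 24 cases with a median of -0.66 (adjusted p = 0.0397, adjusted p = 0.736 with an estimated correlation), with FOSB at -1.93 ± 0.81. IFIT3 was at 0.85 without resistant 4 Gy array 3, EPHB3 at 0.78 without parental 4 Gy array 3 and ATF4 at -0.45 without resistant 4 Gy array 2.

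By limma, 0 of 17976 genes passed for the difference of responses, and the smallest adjusted p was 0.899. At an unadjusted p under 0.05 lay 709 genes, 134 positive and 575 negative, fewer than the 899 expected with no difference. Once parental 4 Gy array 1 was left out, 303 genes passed, but arrays 2 and 3 of that group shared a slide, which could not be told apart from the dose. Without parental 4 Gy arrays 2 and 3, which left 1 array in that group, the medians were 0.40 for G2/M, 0.23 for replication and 0.00 for Wnt targets. The calls of replication, break repair, immediate early genes, the unfolded protein response and Wnt targets were lost there. Leaving out parental 4 Gy array 3 alone lost 4 of the 7 calls. When resistant 4 Gy array 3 was left out, 2 of the 7 were lost, that of the interferon list at 0.35 (adjusted p = 0.0565) and that of immediate early genes at -0.56 (adjusted p = 0.126). With slide as a fixed block 1 of the 7 calls was kept and 3 turned against all other genes, with G2/M at 0.24. With scan day as a fixed block, added after the data were seen, 2 of 7 were kept, and G2/M was at 0.62. Parental 4 Gy arrays 2 and 3 were alone on their slide and scan day. Either block takes them up and leaves array 1 to stand for that group, so the lost calls do not part batch from response.

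The mean of both 4 Gy responses was negative for all 36 G2/M genes with a median of -1.41 (adjusted p = 7.99e-24, adjusted p = 0.331 with an estimated correlation). The mean was negative for all 36 replication genes with a median of -0.82 (adjusted p = 2.26e-15, adjusted p = 0.391 with an estimated correlation) and for 32 of 37 break repair genes with a median of -0.40 (adjusted p = 1.06e-08, adjusted p = 0.331 with an estimated correlation). KIF14, a kinesin of cytokinesis, had a mean response of -1.54 ± 0.50 and POLE2, a subunit of DNA polymerase epsilon, one of -1.14 ± 0.48. KIF14 was at -0.99 and POLE2 at -0.71 without parental 4 Gy array 3. Wnt targets were lower in 23 of 26 cases with a median of -0.43 (adjusted p = 1.25e-06, adjusted p = 0.331 with an estimated correlation). MYC was at -0.57 ± 0.20 and AXIN2 at -0.58 ± 0.30. The level of AXIN2 was 0.556 on parental 4 Gy array 3, against 1.863 and 1.645 on arrays 1 and 2. Stem cell markers were lower in 15 of 20 cases with a median of -0.23 (adjusted p = 0.00230, adjusted p = 0.138 with an estimated correlation). TERT had a mean response of -0.68 ± 0.20 and LRIG1, a regulator of stem cell growth signals, one of -0.83 ± 0.30. Interferon-stimulated genes were higher in 27 of 34 cases with a median of 0.28 (adjusted p = 0.0318, adjusted p = 0.697 with an estimated correlation). IRF7, a transcription factor of interferon induction, had a mean response of 1.03 ± 0.31.

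By limma, 0 of 17976 genes passed for the mean response, and the smallest adjusted p was 0.551. At an unadjusted p under 0.05 lay 1626 genes, 1124 higher and 502 lower. Once parental 4 Gy array 1 was left out, 674 genes passed, with arrays 2 and 3 of 1 slide alone standing for irradiated parental cells. Without parental 4 Gy arrays 2 and 3, which left 1 array in that group, the medians were -0.44 for G2/M and -0.32 for replication. The Wnt call was lost there, at -0.07. The interferon call was lost without resistant 4 Gy array 3, at 0.15 (adjusted p = 0.393), and without parental 0 Gy array 1, at 0.27 (adjusted p = 0.0915).

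Across the 17976 genes, which are not independent replicates, the differences between the lines with and without 4 Gy correlated at a Pearson r of 0.511 and a Spearman rho of 0.559. The sign was the same in 71.9% of genes. This r was 0.225 with quantile scaling and 0.216 with slide run as a covariate, and leaving out 1 array gave 0.3005 to 0.610. The comparisons used separate arrays. LEF1 differed by 1.56 ± 0.60 without and 2.05 ± 0.60 with 4 Gy, UMPS by 0.68 ± 0.30 and 1.09 ± 0.30. The 4 Gy responses of parental and resistant cells correlated at a Pearson r of 0.133 and a Spearman rho of 0.164, with the same sign in 57.1% of genes. The value of r was -0.03 without resistant 4 Gy array 1 and -0.04 without resistant 0 Gy array 2. CENPE, at -2.67 ± 0.64 in parental and -0.54 ± 0.64 in resistant cells, was among the genes with the same sign, and in resistant cells it was at -0.31 without resistant 4 Gy array 3.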

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

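The tests of exchanged labels, of slides and of the responses to 4 Gy were chosen only after the results were seen, whereas the tests of level-matched genes, of the next most frequent way to part the arrays and of other splits of the samples were written before theirs. The test of the difference between the lines in the response to 4 Gy called 7 gene lists, a number that other splits of the samples reached too. The list medians of the resistant minus the parental response were 1.31 for DNA replication, 0.39 for double-strand break repair, 2.37 for G2/M and mitosis, -0.66 for immediate early genes, 0.64 for interferon-stimulated genes, -0.57 for the unfolded protein response and 0.45 for Wnt target genes. None of the 7 was called with an estimated correlation, where the smallest adjusted p was 0.720. Single outlying arrays were not tested within the groups of 3.

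In many genes, PRAC1, H19 and CEACAM6 among them, parental 0 Gy array 2 had the levels of the resistant and resistant 4 Gy array 1 those of the parental cells. Gaps by chance were argued against at a gap over 2 log2 units, where all 16 genes parted the 12 arrays in the same way and the next most frequent way held 0, but at a gap over 1, 99 of 133 genes did and the next of 13 ways held 20, more than the tenth set beforehand. A slide batch was also argued against, since 3 of the 5 slides with more than 1 array held arrays of both sides, among them the slide that the 2 crossing arrays shared. Exchanged labels of these 2 arrays may account for the pattern, since only 1 of the 36 exchanges of a parental with a resistant array gave as many called genes, 313 without irradiation and 3789 after 4 Gy, against 0 and 0 with each of the other 35. That test was found and run on the same data, so that the exchange stays a hypothesis, and a mixture of cultures or a change of clones within a line was not tested.

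Genes of G2/M and replication were low on parental 4 Gy arrays 2 and 3, with G2/M medians of -1.55 and -4.24. Compression of bright signals on their slide was argued against, since genes matched on level differed from unirradiated parental arrays by a median of -0.20 (quartiles -0.61 and 0.26), against -3.60 (quartiles -3.91 and -3.12) for G2/M genes. A slide batch and a response of parental cells to 4 Gy cannot be told apart, because the parental 4 Gy array of another slide had a G2/M median of -0.16, next to the -0.15 to 0.88 of the unirradiated parental arrays. Of the 2 arrays, array 3 was far lower than array 2 although they shared the slide, and the difference within the slide was not tested.

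Interferon-stimulated genes were high on resistant 4 Gy array 3, with a median of 1.03. A slide batch was argued against, since the other array of its slide had a median of -0.52, below the -0.46 to 0.05 of the other resistant arrays. A response to 4 Gy in resistant cells stays open. Of the other 2 irradiated resistant arrays, array 1 lay at -0.15, within the -0.52 to -0.02 of the unirradiated ones, but it carried parental levels in many genes. Array 2 reached 0.05, above that range. A difference between passages was not tested.

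For the comparisons of 3 with 3 arrays there are 10 splits, too few for a share under 0.05, and only the real value and the highest other can be set side by side. Where the real count of genes was 0, every split reached it, so that this count decides nothing. Between the unirradiated lines, 10 of 10 splits gave at least the real 0 genes past the threshold, with 0 the highest other, 5 at least the 308 genes at an unadjusted p under 0.05, with 1029 the highest other, 2 at least the 9 lists, with 9 the highest other, and 4 a Wnt target median of at least 0.15 in size, with 0.19 the highest other. Between the lines after 4 Gy the numbers were 10 for 0 genes, with 0 the highest other, 2 for 4627 genes, with 4758 the highest other, and 8 for 6 lists, with 10 the highest other. For 4 Gy in parental cells they were 10 for 0 genes, with 1171 the highest other, 3 for 2522 genes, with 4831 the highest other, and 10 for 4 lists, with 10 the highest other. For 4 Gy in resistant cells they were 10 for 0 genes, with 0 the highest other, 7 for 171 genes, with 897 the highest other, and 2 for 10 lists, with 10 the highest other.

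Some other splits of the parental arrays called many genes. Both splits named next keep parental 4 Gy arrays 2 and 3 together, as the real split does, so that they do not part a structure of the samples from the dose. The split that follows the slide run, parental 0 Gy array 1 with parental 4 Gy arrays 2 and 3, called 893 genes, against 0 for the real one. More, 1171, came from the split of parental 0 Gy arrays 1 and 2 with parental 4 Gy array 1 from the rest, which does not follow the slide run. It does follow the negative control signal. That signal was 96.6, 152 and 137 on parental 0 Gy array 3 and parental 4 Gy arrays 2 and 3, against 18.6 to 51.5 on the other side. An effect of background was not tested. The fit of 4 Gy in parental cells with slide run as a covariate gave 0 genes. For the difference of the responses, 100 of 100 drawn splits reached the real 0 genes by necessity, with 612 the highest other, 45 at least 709 genes at an unadjusted p under 0.05, with 3704 the highest other, and 54 at least 7 lists, with 14 the highest other. For the mean response, 100 of 100 likewise reached 0 genes, with 854 the highest other, 22 at least 1626 genes, with 3614 the highest other, and 70 at least 6 lists, with 14 the highest other. By the counts at an unadjusted p and of lists, chance was not excluded for either.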

How the results depend on the processing

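Scan day as a block and the fits without pairs of arrays were chosen only after the data were seen. The counts of genes past the threshold were 0 in all 6 comparisons, so that stricter thresholds on the same fit gave 0 by necessity. They stayed 0 with quantile scaling, normexp, both filters, each probe by itself, the deposited value table, slide, slide run, scan day and the replicate block. Median scaling gave 177 genes between the irradiated lines (74 higher, 103 lower), 29 for 4 Gy in parental cells and 9 results of named genes, counted over the 6 comparisons, and array weights gave 2315 between the irradiated lines and 27 results of named genes. Leaving out each array gave 0 to 4679 genes between the irradiated lines, 0 to 2465 for 4 Gy in parental cells, 0 to 303 for the difference of responses, 0 to 674 for the mean response and 0 to 92 results of named genes, and in each the highest value came without parental 4 Gy array 1. Without parental 0 Gy array 2 and resistant 4 Gy array 1, 11 genes passed between the unirradiated and 70 between the irradiated lines, and 1 result of a named gene. The cause was not tested. Without parental 4 Gy array 1 its group was arrays 2 and 3, which shared a slide, so slide could not be told apart from line or dose. The median of all genes moved with median scaling from -0.07 to 0.43 and from -0.12 to 0.57 between the lines without and with 4 Gy, from 0.08 to -0.24 for 4 Gy in parental cells, from -0.04 to 0.16 for the difference of responses and from 0.07 to -0.15 for the mean response. It lay between -0.07 and 0.07 with quantile scaling, normexp and the value table.

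Of 42 list calls, 0 were kept with an estimated correlation and 1 with fry, 22 with slide as a fixed block, 28 with scan day as a fixed block, 31 with quantile scaling, 41 with the replicate block, 33 without the 2 arrays that cross the labels and 32 without parental 4 Gy arrays 2 and 3. Leaving out each array kept 33 (without resistant 4 Gy array 1) to 42 of them, and gave 34 to 49 calls in all, new ones included. A fixed slide or scan day block takes up parental 0 Gy array 1, resistant 4 Gy array 2 and the pair of parental 4 Gy arrays 2 and 3. Each had its slide and scan day to itself, so calls lost with these blocks do not part batch from line or dose. The Wnt target median between the unirradiated lines, 0.15, was not called at 0.17 with quantile scaling, 0.15 with normexp, -0.049 with slide run, 0.16 without parental 0 Gy array 3, 0.094 without resistant 0 Gy array 2, 0.15 with an estimated correlation and 0.15 with fry, with adjusted p from 0.121 to 0.970, and ranged from 0.09 to 0.24 over arrays left out. Turned directions, in the median or in the test beside all other genes, were those of replication between the unirradiated lines with scan day as a fixed block, at -0.12, and of G2/M there with slide run, at -0.27. Between the irradiated lines slide as a fixed block gave 0.28 for G2/M, 0.23 for break repair and 0.10 for Wnt targets, and for the difference of responses 0.24, 0.18 and 0.003. Wnt targets turned there also with scan day as a fixed block, at 0.13, and without parental 4 Gy arrays 2 and 3, at 0.00, and replication after 4 Gy in resistant cells without resistant 4 Gy array 1, at 0.10, and without the 2 arrays that cross the labels, at 0.10. Over arrays left out that replication median ranged from -0.30 (without resistant 4 Gy array 2) to 0.10.

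The correlation of the line differences with and without 4 Gy, 0.511, was 0.225 with quantile scaling, 0.417 with normexp, 0.216 with slide run, 0.676 without the 2 arrays that cross the labels, 0.414 without parental 4 Gy arrays 2 and 3, and 0.3005 (without parental 0 Gy array 1) to 0.610 (without resistant 4 Gy array 1) over arrays left out. That of the 4 Gy responses, 0.133, ranged from -0.0417 without resistant 0 Gy array 2, over -0.0271 without resistant 4 Gy array 1, to 0.274 without resistant 0 Gy array 3. The replicate numbers showed no clear pairing of arrays: of 18 pairs of the same number 7 had a correlation of deviations over 0.1, from -0.396 to 0.537, and the replicate block gave 0 genes in each comparison. Genes whose log2 level lay under the lowest level well above background, -7.42 to -4.96 by array, were not well above background, and their differences are uncertain in size. Fits of only the 6 arrays compared were not run for the difference of responses and the mean response, and list tests were not run with each probe by itself.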

Other observations

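The list tests below were planned, whereas the counts of probes of opposite sign were chosen only after the results were seen. Gene groups of cell identity and signalling without a call showed values of either sign between the unirradiated lines. Goblet cell genes had a median of -0.30 (adjusted p = 0.321), lower in 14 of 20 cases, and enteroendocrine genes one of -0.64 (adjusted p = 0.228), lower in 9 of 11. Epithelial genes had a median of -0.13 (adjusted p = 0.679), lower in 19 of 30, and mesenchymal genes one of -0.06 (adjusted p = 0.649) with 4 of 8 lower. Notch pathway genes had a median of -0.04 (adjusted p = 0.518), and receptor tyrosine kinase and RAS pathway genes one of 0.02 (adjusted p = 0.441). Interferon-stimulated genes, lower in 24 of 34 cases, had a median of -0.30 (adjusted p = 0.0770) and BMP and TGF-beta genes, higher in 13 of 23, one of 0.08 (adjusted p = 0.0910).

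Stress and death pathways were not called between the unirradiated lines either. The unfolded protein response had a median of 0.13 (adjusted p = 0.0770), higher in 17 of 24 cases, hypoxia and glycolysis genes one of 0.13 (adjusted p = 0.321), NF-kappaB and inflammatory genes one of 0.08 (adjusted p = 0.340), immediate early genes one of 0.01 (adjusted p = 0.670), apoptosis regulators one of -0.04 (adjusted p = 0.641), histone genes one of 0.09 (adjusted p = 0.397) and cholesterol synthesis genes one of -0.14 (adjusted p = 0.577). The means of the hypoxia and immediate early lists, -0.02 and -0.04, had the opposite sign, and the apoptosis, mesenchymal and Notch tests pointed up against a negative median. After 4 Gy in resistant cells CDKN1A differed by -0.05 ± 0.57 and MDM2 by -0.18 ± 0.28 with its probes of opposite sign. After 4 Gy in parental cells DDIT3, a mediator of death under stress of the endoplasmic reticulum, stood at 2.31 ± 2.04 against 0.14 ± 0.72 without, and the unfolded protein response had a median of 0.65, higher in 21 of 24 cases (adjusted p = 0.0543). Parental 4 Gy array 3, on the slide with a high signal of negative controls, carried most of both, with DDIT3 at 0.55, 1.85 and 4.55 on arrays 1, 2 and 3 and list medians of -0.20, 0.10 and 1.32.

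Markers of other cell types were not called after 4 Gy in parental cells, where blood cell markers, higher in 12 of 15 cases, had a median of 0.78 (adjusted p = 0.0791), endothelial and neural markers, higher in 6 of 6, one of 0.97 (adjusted p = 0.0707), and fibroblast and stromal markers, higher in 3 of 5, one of 0.64 (adjusted p = 0.644). Parental 4 Gy arrays 2 and 3, where these markers were highest, had the highest negative control signals, 152 and 137. By the extraction software, 3 arrays were in range, parental 0 Gy arrays 1 and 2 and resistant 4 Gy array 2, and the other 9 were marked for evaluation. Of the genes with 2 or more tested probes and an unadjusted p under 0.05, 4 of 41 between the unirradiated lines and 166 of 704 between the irradiated lines had a probe of opposite sign. The numbers were 71 of 322 for 4 Gy in parental and 3 of 37 in resistant cells, 24 of 57 for the difference of responses and 44 of 231 for the mean response.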
